A study of Mus musculus with 2 samples.

How the data were processed

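RNA sequencing had been carried out on 2 libraries of RAW264.7 cells, a mouse macrophage-like cell line that forms osteoclasts when given RANKL, the cytokine that drives osteoclast differentiation. One library came from cells with a control shRNA and the other from cells with an shRNA against Cpeb4. Per the labels' protocols, both cultures were seeded at 7500 cells per cm2 and received 100 ng/ml RANKL 24 h later. The series title gives day 3 as the time of collection. The labels name no cultures, clones or batches, and whether the RNA was selected for poly(A) tails, and whether the kit marked strand, is not given in the sources used here.

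The deposited table held whole-number read counts per gene, with 1 column per library. Per the submitters' processing notes, reads were aligned with HISAT2 to mouse genome build mm10. The HISAT2 version, the counting tool, its handling of strand and of reads with several alignments, and the gene annotation are not given in the sources used here. The table listed 18987 genes, each with at least 1 count in both libraries. Genes without a count in 1 library or in both are therefore not analysed here. Any gene detected in only 1 library is thus missing from the ranks, gene counts and lists below. Genes at 4 counts were more frequent than those at 3 or 5 counts (585 against 444 and 286 in the control library, 364 against 282 and 205 in the Cpeb4 shRNA library), so the values may be estimates rather than plain read tallies. Counts may be divided among copies. The nuclear copy Gm10925 had 235505 control counts beside 223763 for mt-Atp6, and Gm28437 had 239189 beside 238209 for mt-Co3. Genes with near-identical copies, among them mitochondrial and ribosomal protein genes, and overlapping genes are thus uncertain.

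Gene symbols and identifiers were taken from the deposited table. Coordinates, gene types, transcript lengths and 3′ UTR sequences came from GENCODE M21 for GRCm38, the assembly that mm10 names, in which 18935 of the 18987 identifiers were found. A total of 26 symbols were shared by more than 1 identifier, and such genes are printed with the identifier where named.

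Counts were scaled with TMM normalisation in edgeR 4.0.16 (R 4.3.3), which gave factors of 0.922 for the control library and 1.08 for the Cpeb4 shRNA library. CPM values are counts relative to the resulting effective library size. Genes with a mean of at least 1 CPM over both libraries were kept, which left 12086. For each gene the log2 ratio of Cpeb4 shRNA over control was computed. Its 95% interval was the exact Clopper-Pearson interval of the gene's share of the 2 counts. With 1 library per group no test, p-value or standard error was computed, and no difference has a replicate check. The intervals cover counting error only and take the values as read tallies. If the values are estimates, the intervals are approximate. They do not cover variation between cultures or clones, and reads copied by PCR are not independent molecules. Genes were counted as higher or lower by a rule of size, at least 2-fold.

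The total count was 79399680 in the control library and 119350322 in the Cpeb4 shRNA library, a ratio of 1.50. The median width of the counting interval was 0.16 log2 units over genes past the filter. A count of 3 corresponded to 0.041 CPM in the control library and 0.023 CPM in the Cpeb4 shRNA library.

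A set of 29 gene lists was written before the data were examined. For each list with at least 5 members past the filter, the median log2 ratio was ranked among the medians of 10000 random lists of the same size, matched in 20 bins of mean expression. The percentile describes these 2 libraries only. Lists overlap in part and genes within a list are not independent. Named genes followed a rule also written before the data were examined. It took the CPEB genes and the 15 highest and 15 lowest genes by the limit of the counting interval nearest 0, predicted gene models left out. It also took the 2 highest and 2 lowest members of each list and a preset group of osteoclast regulators and effectors. Some genes that the rule takes are not reported here.

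Alternatives were total-count scaling, DESeq2 1.42.0 size factors, upper-quartile scaling, scaling to the median of 20 reference genes, pseudocounts of 0.5 and 2 CPM, and random thinning of the deeper library. Other filters (none, or a mean of at least 10 CPM), other size thresholds (1.5-fold and 4-fold), a threshold on the interval limit, and unmatched random lists were also tried. Restriction to protein-coding genes and removal of the trend with GC content and transcript length were added after seeing the data. The computations were tested on simulated counts for the comparison of the 2 libraries over 18987 genes, of which 200 were changed. All genes changed 3-fold or 8-fold, up or down, passed the 2-fold rule, no unchanged gene did (0), and 95.13% of the intervals of unchanged genes held 0. The simulated counts were Poisson draws with as many genes raised as lowered. They check the computation only, not whether the intervals or the scaling hold for the real libraries. Analyses used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.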

Results

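The data comprised gene counts from 2 libraries of RANKL-treated RAW264.7 cells, 1 with a control shRNA (79399680 counts in total) and 1 with an shRNA against Cpeb4 (119350322 counts). Cpeb4 encodes a cytoplasmic polyadenylation element-binding protein, an RNA-binding protein of the CPEB family. The comparison asks how the transcriptome of cells under osteoclast differentiation differs when Cpeb4 is targeted. There was 1 library per group, so every difference below compares these libraries, without a replicate check or a test.

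The targeted gene was lower in the Cpeb4 shRNA library. Cpeb4 (ENSMUSG00000020300; mm10 chromosome 11, 31872211 to 31935634, plus strand, overlapping no other annotated gene) had 25270 counts, or 345 CPM, in the control library. It had 13491 counts, or 104 CPM, in the Cpeb4 shRNA library. The log2 ratio was -1.73 (95% counting interval -1.76 to -1.70), a 3.31-fold lower level. The paralogs Cpeb2 and Cpeb3 were within 2-fold, with log2 ratios of -0.37 and -0.22, and Cpeb3 was at 0.02 under total-count scaling. Cpeb1 is not analysed here.

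Osteoclast effector genes were lower in the Cpeb4 shRNA library. All 25 members past the filter had a log2 ratio below 0, and 24 were at least 2-fold lower. The median was -2.03, a 4.07-fold difference, and 0 of 10000 expression-matched random lists had a median as low. Ctsk, the collagen-degrading protease of osteoclasts, had 24234 CPM in the control library and 4175 CPM in the Cpeb4 shRNA library (log2 ratio -2.54, counting interval -2.54 to -2.53). Acp5, which encodes tartrate-resistant acid phosphatase, had 15715 and 3304 CPM (-2.25). The lowest ratios belonged to the immunoreceptor gene Oscar (-3.82) and the sodium/proton exchanger gene Slc9b2 (-3.53). Calcr, the calcitonin receptor gene, and the integrin gene Itgb3 followed at -3.49 and -3.41. The gelatinase gene Mmp9 was at -2.03. The fusion genes Dcstamp and Ocstamp were at -1.87 and -1.37, and the proton pump subunit genes Atp6v0d2 and Tcirg1 at -1.49 and -1.06. Car2, a carbonic anhydrase gene, was the member within 2-fold (-0.81). Together the effector genes took 6.18% of all counts in the control library and 1.64% in the Cpeb4 shRNA library.

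Genes of RANK signalling and osteoclast transcription factors had smaller differences. Of 35 members past the filter, 27 were within 2-fold, 4 were higher and 4 were lower. Under TMM scaling 22 were below 0, with a median of -0.28 at percentile 11.3 of matched and 2.26 of unmatched random lists. Nfatc1, the transcription factor required for osteoclast formation, had 1637 and 1578 CPM, a log2 ratio of -0.05 (-0.06 to -0.04), which was 0.18 under total-count scaling and 0.07 after removal of the trend with GC content and length. Fos was at 0.37 (-0.03 under reference-gene scaling), Prdm1 at -0.45 and the RANK receptor gene Tnfrsf11a at -0.79. The kinase gene Syk (-2.15) and the adaptor gene Gab2 (-1.36) had the lowest ratios. Myc (2.86) and the receptor gene Trem2 (1.76) had the highest. Among 25 negative regulators of osteoclastogenesis, 3 were higher, 4 were lower and 18 were within 2-fold. Their median was -0.13, 0.14 under total-count scaling and -0.38 at a mean of at least 10 CPM. Id3 (2.25) and Id2 (1.57), which encode inhibitors of helix-loop-helix factors, were highest. The receptor gene Sirpa (-2.61) and the calcineurin regulator gene Rcan1 (-1.73) were lowest. The repressor genes Bcl6 and Irf8 were at 0.38 and -1.02, the latter from 99 and 86 counts, and Bcl6 at -0.02 under reference-gene scaling.

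**Figure D1:**
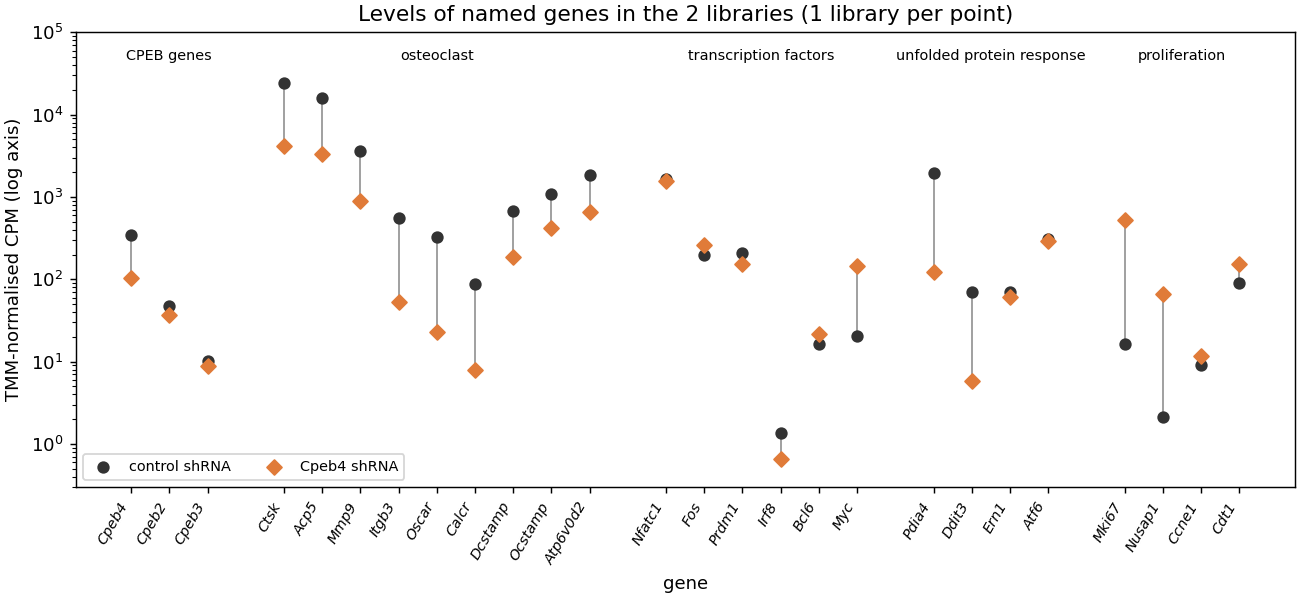
Levels of named genes in the 2 libraries as TMM-normalised CPM on a log axis. Each point is 1 library (circles, control shRNA; diamonds, Cpeb4 shRNA), and a line joins the points of a gene. Nfatc1 lies at 1637 and 1578 CPM, Itgb3 at 561 and 52.6 CPM, and Mki67 at 16.2 and 530 CPM.

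Proliferation genes were higher in the Cpeb4 shRNA library. All 38 members had a log2 ratio above 0 under TMM scaling, and 35 were at least 2-fold higher. Their median was 3.95, a 15.4-fold difference, and 0 of 10000 random lists had a median as high. Mki67, which marks cycling cells, had 1184 counts in the control library and 68525 in the Cpeb4 shRNA library (log2 ratio 5.03, counting interval 4.95 to 5.12). The spindle gene Nusap1 was at 4.98. The cyclin E gene Ccne1 (0.38) and the replication licensing gene Cdt1 (0.77) had the lowest ratios in the list. Under scaling to reference genes Ccne1 lay at -0.03. Cytosolic ribosomal protein genes were also higher, all 51 above 0 and 21 at least 2-fold, with a median of 0.98. They took 2.05% of counts in the control library and 4.77% in the Cpeb4 shRNA library. Rps2 (2.54) and Rpl30 (1.55) were highest, and Rpl38 (0.53) and Rps16 (0.56) lowest. Many of these genes have processed pseudogenes that can share reads.

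Endoplasmic reticulum stress genes were lower. In the list for the unfolded protein response, 19 of 24 members were at least 2-fold lower, 0 were higher, and all were below 0 under TMM scaling. The median was -2.31, and 0 of 10000 random lists had a median as low. Pdia4, a disulfide isomerase gene, had 142475 counts in the control library and 15873 in the Cpeb4 shRNA library (-3.99). The stress-induced transcription factor gene Ddit3 was at -3.57. The sensor genes Ern1 and Atf6 were at -0.19 and -0.08, and total-count scaling placed them above 0, at 0.04 and 0.15. Targets of ATF4, the transcription factor of the amino acid response, went both ways, with 4 higher, 5 lower and 15 within 2-fold of 24. Their median was -0.15, and 0.09 under total-count scaling. The amino acid transporter gene Slc7a5 (2.73) and the serine synthesis gene Psat1 (2.28) were highest. Trib3 (-2.11) and Nupr1 (-1.76) were lowest.

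**Figure D2:**
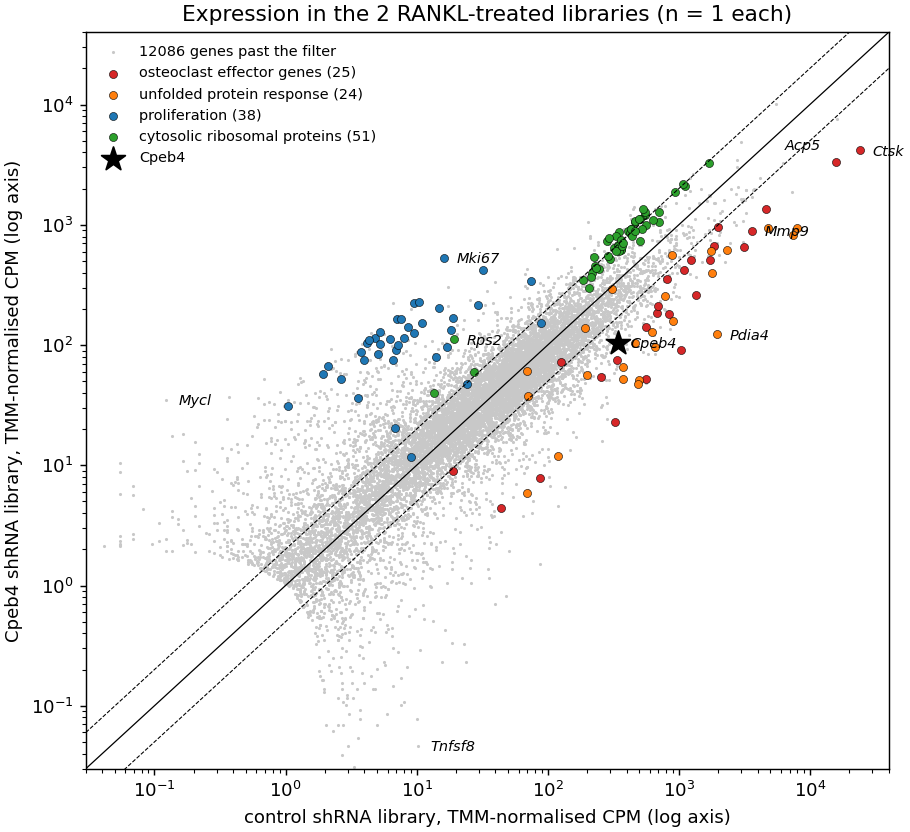
TMM-normalised CPM of each gene past the filter in the control shRNA library (x axis, log) and the Cpeb4 shRNA library (y axis, log), 1 library each. The solid line marks equal levels and the dashed lines 2-fold differences. All 25 osteoclast effector genes lie below the line of equality and all 38 proliferation genes above it under TMM scaling.

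Lysosome and autophagy genes were mostly lower, with 23 of 39 at least 2-fold lower, 3 higher and a median of -1.07. Random lists were as low in 0 of 10000 draws. Hexa (-2.18) and Gla (-2.17), which encode lysosomal glycosidases, were lowest. The cathepsin genes Ctsc (3.85) and Ctss (2.46) were highest. Genes of cell fusion and adhesion had a median of -0.88, with 11 of 24 lower and 3 higher (3 of 10000 random lists were as low). The tetraspanin gene Tspan7 (-5.31) and the integrin gene Itgax (-4.67) were lowest. The lipid transporter gene Mfsd2a (5.55, from 4 and 332 counts) and the metalloprotease gene Adam8 (2.62) were highest. Cytoskeleton and podosome genes had a median of -0.46 at percentile 7.91 (0.17 of unmatched lists), with 8 of 31 lower, among them Rhou (-2.73) and Ptk2b (-1.86). The actin-bundling gene Fscn1 was higher (2.13), and the ubiquitin ligase gene Cbl followed at 0.57.

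All 15 mitochondrially encoded genes were below 0, with a median of -0.91 and 2 at least 2-fold lower, mt-Atp8 (-1.22) and mt-Co1 (-1.10). The smallest differences were those of mt-Nd3 (-0.41) and mt-Co3 (-0.75). Total-count and reference-gene scaling placed this list's median at -0.68 and -1.32. All 37 nuclear genes of oxidative phosphorylation were within 2-fold and below 0 under TMM scaling (median -0.52, percentile 3.71 of matched and 0.06 of unmatched lists). They ranged from -0.83 for Ndufa1 and -0.82 for Uqcrc1 to -0.19 for Ndufb5 and -0.14 for Atp5o. The last pair lay at 0.04 and 0.09 under total-count scaling. Glycolysis genes had a median of -0.37 at percentile 9.29 (1.64 of unmatched lists), with 2 of 24 higher and 1 lower. The glucose transporter gene Slc2a3 was at 5.03 from 21 and 1215 counts, the lactate transporter gene Slc16a1 at 1.80, Bnip3 at -2.08 and Aldoc at -0.98. Cholesterol and fatty acid synthesis genes had a median of -0.50 at percentile 0.44, with 6 of 30 lower and 2 higher. The sterol genes Insig1 (-1.78) and Dhcr7 (-1.28) were lowest, and the fatty acid genes Fads2 (2.30) and Elovl6 (1.86) highest. Antioxidant genes and NRF2 targets had a median of 0.02, which was below 0 under 4 alternatives (-0.39 with reference-gene scaling). Of these 23 genes 21 were within 2-fold. G6pdx was at 1.15, Sod1 at 0.99, Me1 at -1.74 and Ftl1 at -0.86.

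Genes of RNA processing were higher as lists, mostly by less than 2-fold. Splicing factors and nuclear speckle genes had a median of 0.70, with 9 of 43 higher and 0 lower, and 0 of 10000 random lists had a median as high. Celf2 (4.66) and Hnrnpa1 (2.01) were highest. The nuclear RNA Neat1 (-0.92) and the splicing factor gene Mbnl2 (-0.91) were lowest. Polyadenylation, deadenylation and mRNA stability factors had a median of 0.36 at percentile 99.8, with 8 of 44 higher and 2 lower, and a median of -0.045 under reference-gene scaling. Btg2 (2.08) and Btg1 (1.82), both antiproliferative genes whose proteins bind deadenylases, were highest. Zfp36l1 (-1.13) and Tent5a (-1.04) were lowest.

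Interferon response genes had a median of 0.77, with 10 of 25 higher, 0 lower and 47 of 10000 random lists as high. At a mean of at least 10 CPM the median was 0.34. The RNA sensor genes Ifih1 (8.02-fold, from 40 and 567 counts) and Dhx58 (3.94-fold, from 32 and 223 counts) were highest, and Slfn5 (log2 ratio -0.73) and Eif2ak2 (-0.14, and 0.09 under total-count scaling) lowest. Inflammatory cytokine and chemokine genes numbered 8 past the filter, 2 higher and 3 lower. Their median of 0.26 was -0.05 under reference-gene scaling. At a mean of at least 10 CPM the median was -1.47, the value of Spp1, since Tnf, Il18 and Il1rn among others drop out there. Among the 8, Il18 (2.70) and Tnf (1.92) were highest. Il1rn (887 and 196 counts) and Vegfa (-1.60) were lowest. Among 15 macrophage identity genes the median was -0.28 at percentile 9.37, with 3 higher and 2 lower. It was -0.03 without a filter and -0.53 at a mean of at least 10 CPM. Cd40 (2.89) and the scavenger receptor gene Cd36 (2.25) were highest, and Apoe (-2.33) and Cd68 (-1.04) lowest. Targets of p53 and apoptosis genes had a median of -0.51, with 6 of 21 lower and 2 higher (percentile 0.43). Bid (1.76) and Trp53 (1.67) were highest, and Trp53inp1 (-2.84) and Phlda3 (-2.50) lowest. Immediate early and heat shock genes had a median of 0.30, which was -0.34 under reference-gene scaling and -0.08 at a mean of at least 10 CPM. Of these 22 genes 5 were higher and 2 lower. The heat shock gene Hspa1b (2.41) and Btg2 (2.08) were highest. Egr1 (-3.59) and Nr4a1 (-2.01) were lowest.

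The fixed histone list held 30 symbols, some of them older and newer names of the same gene. Of these symbols 11 were in the table and 8 passed the filter, 1 higher and 3 lower, with a median of -0.92. The median was -1.70 without a filter and -0.35 at a mean of at least 10 CPM. H2bc4 (-2.28) and H1f4 (-2.47), replication-dependent histone genes, were lowest. The variant genes H2az1 (1.46) and H3f3b (0.44) were highest. The 20 reference genes had a median of 0.41 under TMM scaling (percentile 99.3 of matched and 94.3 of unmatched lists), with Rplp0 at 1.01 and Tubb5 at 1.93. The transferrin receptor gene Tfrc (-1.96) and Gusb (-0.75) were lowest. Of markers of other cell types, the table, which lists genes with a count in both libraries, held 0 of 18 for granulocytes and mast cells. Of fibroblast and osteoblast markers 6 of 19 were listed, of lymphoid markers 3 of 16, and 0 of either passed the filter. Of 16 dendritic cell markers 5 passed, with a median of -0.52, 1 higher and 2 lower. At a mean of at least 10 CPM the median was -2.60, but Irf4, Zbtb46 and Fscn1 drop out there, so Itgax weighs heavily. Among the 5, Itgax (-4.67) and Irf4 (-1.07) were lowest, Fscn1 (2.13) was highest, and Zbtb46 was at -0.42.

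**Figure D3:**
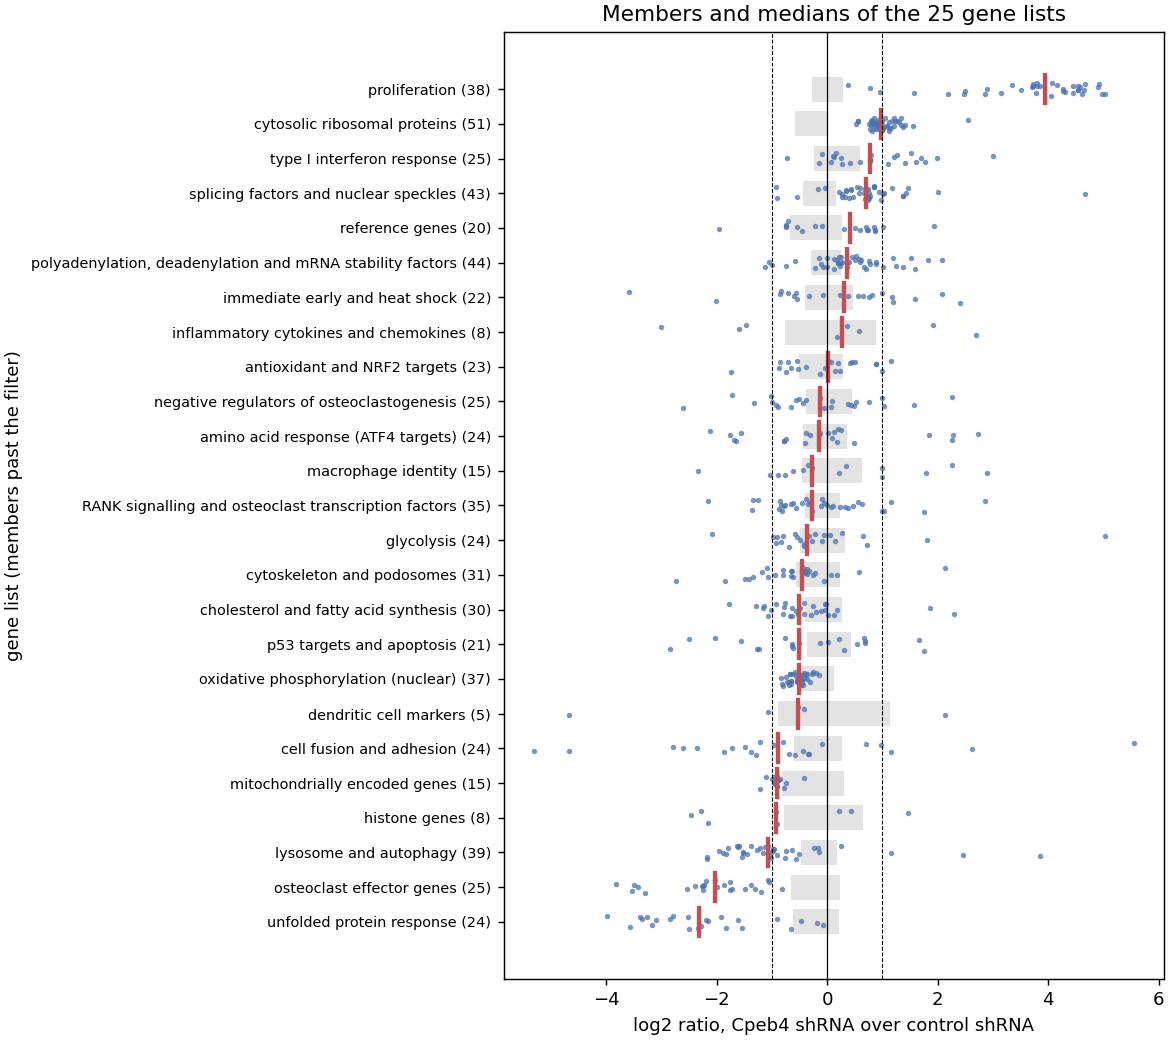
Log2 ratios of Cpeb4 shRNA over control (x axis) for the members past the filter of each gene list (rows, number of members in parentheses). Points are genes, red bars list medians, and grey boxes the middle 95% of medians of 10000 expression-matched random lists. Dashed lines mark 2-fold. The medians run from -2.31 for the unfolded protein response to 3.95 for proliferation.

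Over all 12086 genes past the filter, 1765 were at least 2-fold higher and 1421 at least 2-fold lower in the Cpeb4 shRNA library, and 8900 were within 2-fold. At least 4-fold differences were seen for 582 higher and 426 lower genes. Among the highest by counting interval, the transcription factor gene Mycl (ENSMUSG00000028654; chromosome 4, 122995652 to 123002485) had 9 and 4547 counts (log2 ratio 8.16, 7.23 to 9.29). The kinase gene Map3k15 (7.59, from 4 and 1358 counts) and the actin-severing protein gene Scin (6.66) were also among them. So was the phospholipid flippase gene Atp8b4 (7.33, from 4 and 1134 counts). Gja1, a connexin gene, was at 6.25 and the proteoglycan gene Cspg4 at 6.04. The kinetochore genes Cenpf and Nuf2 were at 5.38 and 5.48. Odf3l1 (6.10), Tmem176b (5.88), Lrr1 (6.72, from 4 and 744 counts), Adgrl2 (5.56) and Depdc1a (5.83) were also in this group. It also held ENSMUSG00000115018 (6.99), an identifier with the symbol Ndor1 that overlaps another gene and is uncertain. Map3k15, Tmem176b, Adgrl2 and Cenpf overlap another annotated gene too.

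At the other end was Tnfsf8 (ENSMUSG00000028362; chromosome 4, 63831308 to 63861347), a TNF superfamily ligand gene, with 747 and 6 counts (log2 ratio -7.78, -9.23 to -6.65). Mzb1, which encodes an endoplasmic reticulum protein, was at -7.03, and the KDEL receptor gene Kdelr3 at -6.74 from 242 and 4 counts. The calcineurin regulator gene Rcan2 (-6.16), the focal adhesion gene Tns1 (-5.88), the folate enzyme gene Aldh1l1 (-5.84) and the histone gene H2ac18 (-5.86) were similarly low. So were Pla2g7 (-6.24), Psd4 (-6.08), Mtus1 (-5.81), Septin5 (-6.12), Vopp1 (-6.04), Pcdhb15 (-6.13), Cd84 (-5.27) and Tmem98 (-5.49). Of these lowest genes, Tnfsf8, Tns1, Psd4, Cd84 and Tmem98 overlap no other annotated gene, and the others do. Genes at 4 counts were more frequent than those at 3 or 5 counts in both libraries, so the sizes for genes with so few counts are uncertain.

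The balance of higher and lower genes depended on scaling. TMM scaling gave 55.4% higher among genes past 2-fold. Total-count scaling moved every log2 ratio by 0.23 and gave 2510 higher and 1027 lower genes (71.0% higher). Scaling to reference genes moved every ratio by -0.41 and gave 998 higher and 2606 lower (27.7% higher).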

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

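Removal of the trend with GC content and transcript length and restriction to protein-coding genes were chosen after seeing the data. No paired analysis was possible because each group had 1 library and no result comes from a test. Cpeb4 stayed below 0 under each other scaling, both pseudocounts, thinning and trend removal, at -1.49 with total-count scaling, -1.76 with upper-quartile scaling and with thinning, -2.13 with reference-gene scaling and -1.89 after trend removal. Gene counts at least 2-fold higher and lower were 998 and 2606 with reference-gene scaling, 3217 and 2930 without a filter, and 1025 and 907 at a mean of 10 CPM. They were 3191 and 2674 at 1.5-fold and 582 and 426 at 4-fold. The construction of these filters and thresholds sets those changes. With reference-gene scaling, which subtracts the reference median from every ratio, list medians were -2.43 for osteoclast effectors, -0.69 for RANK signalling, 3.54 for proliferation, 0.29 for splicing and 0.57 for ribosomal proteins. They were -1.47 for lysosome, -0.78 for glycolysis, -0.92 for oxidative phosphorylation, -0.91 for cholesterol synthesis, -0.87 for cytoskeleton and -1.32 for mitochondrially encoded genes. The mRNA stability list turned to -0.045. With total-count scaling, medians were 0.59 for mRNA stability, 0.93 for splicing, 1.21 for ribosomal proteins, -0.83 for lysosome, -0.29 for oxidative phosphorylation, -0.05 for RANK signalling, -0.14 for glycolysis, -0.27 for cholesterol synthesis, -0.23 for cytoskeleton and -0.68 for mitochondrially encoded genes. A pseudocount of 2 CPM gave 3.60 for proliferation, since it shrinks genes low in the control library. Trend removal gave -1.13 for mitochondrially encoded genes. It subtracts the median ratio of genes of like GC content and then of like length, and that subtraction sets the change. Unmatched random lists moved 5 lists across the limits of the middle 95% of random medians. RANK signalling, glycolysis, oxidative phosphorylation and cytoskeleton genes moved to percentiles 2.26, 1.64, 0.06 and 0.17, and reference genes to 94.3. The matching on expression sets these differences. Of 275 recomputed list medians 264 kept their sign, and 6 of 25 lists turned in some setting. Of 1144 recomputed values of 143 named genes, 492 left their counting interval, and 0 of the genes past 2-fold turned. After thinning, 218 genes stood at the floor of 3 counts. Depth limits genes with few counts, whose intervals span more than 2 log2 units for Tnfsf8.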

Other observations

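The gene families, the neighbouring gene pairs, the wider small RNA set, the test for a common ratio and the rank of Cpeb4 among effector genes were chosen after their values were seen. The tests on GC content and length, on non-polyadenylated RNA past the filter and on the 3′ UTR motif were added after seeing the data, but before their own outcomes were seen.

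Nucleoporin genes, which encode the nuclear pore, had a median log2 ratio of 1.26, with 26 of 27 above 0 and 15 at least 2-fold higher in the Cpeb4 shRNA library. Nup210 was highest at 3.92. All 12 identifiers of small nucleolar RNA host genes were above 0, with a median of 1.52. They include Snhg4 (2.25) and a further identifier with that symbol, ENSMUSG00000117694 (2.78). Genes with Nop, Nol and Utp symbols, mostly of ribosome biogenesis, had a median of 0.65, with 25 of 27 above 0. Nop56 (1.71) and Nop58 (1.69) were highest. These medians stayed above 0 under total-count scaling and under reference-gene scaling, which gave 0.85, 1.11 and 0.24.

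Secretory pathway genes of the Sec and Tmed families went the other way, with a median of -0.59, 30 of 33 below 0 and 6 at least 2-fold lower, and -0.36 under total-count scaling. Sec13 is in this set and among the nucleoporin genes. TNF receptor superfamily genes had a median of -1.07, with 5 of 10 at least 2-fold lower, among them Tnfrsf1b (-2.63). Of 6 beta protocadherin genes 5 were at least 2-fold lower, with a median of -4.34. They are near-identical in part and may share reads, and the members ranged from -6.13 to -0.68. Total-count scaling left the median at -4.11. Of the metallothionein genes, Mt3 was at -4.04, Mt2 at -1.58 and Mt1 at -0.75. Mfsd2a (chromosome 4, 122946850 to 122961188) and Mycl (122995652 to 123002485), at 5.55 and 8.16, lie close together in the genome. So do Odf3l1 (chromosome 9, 56848659 to 56864679) and Cspg4 (56865033 to 56899870), at 6.10 and 6.04. These pairs are examples, not a full list.

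Osteoclast effector genes were lower and proliferation genes higher in the Cpeb4 shRNA library. Removal of the trend with GC content and length left the effector median at -2.02 and the proliferation median at 3.98, which argues against such a trend as the whole cause. Dilution by cells that lack osteoclast transcripts predicts 1 common ratio for effector genes, and 52.0% of them (13 of 25) had counting intervals wholly beyond 0.5 log2 units of the median. Those intervals hold no variation between cultures, so this does not exclude dilution. Dilution, an earlier differentiation stage of the Cpeb4 shRNA culture, a shift in the mix of cells that each express some effector genes, an effect of this shRNA or culture, and loss of Cpeb4 remain open, since 1 library per group confounds them. Whether the lower Cpeb4 count comes from the shRNA or follows the lower osteoclast state cannot be told apart. The ratios of 17 of the 25 effector genes lay below that of Cpeb4, a rank that either explanation allows.

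Replication-dependent histone genes went against the proliferation genes. All 22 past the filter (of 51 in the table) were lower in the Cpeb4 shRNA library, with a median of -2.41 and 21 at least 2-fold lower. All 22 stayed below 0 under total-count (-2.18) and reference-gene scaling (-2.82). The histone variant genes H2az1 (1.46) and H2az2 (2.43) were higher. Most replication-dependent histone mRNAs lack a poly(A) tail, so a lower yield of such RNA may account for the pattern, but 1 eligible small RNA gene passed the filter (Rn7sk, 0.61), too few to decide. A wider set of 11 small RNA genes with at least 20 counts had a median of 0.24 (interval of the median -1.11 to 1.15), with 4 below 0 and a range from -1.47 to 1.88. All 4 small RNA genes past the filter, of which some overlap other genes, lay between -0.22 and 0.61. The interval of the wider set's median reaches down to -1.11, and these values rest on few counts or on overlapping genes, so they do not decide. Whether the RNA was selected for poly(A) tails is also not known. A lower yield therefore cannot be told apart from lower histone transcript levels or from another cause.

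CPEB proteins bind U-rich elements in 3′ UTRs, so a hypothesis is that transcripts with TTTTAT or TTTTAAT differ in abundance. Of 10425 genes searched, 6594 had the motif, with a median log2 ratio of 0.06. That median lay 0.02 (0.0195) above that of random gene lists matched on 3′ UTR length and GC content. TTTTAT alone gave 0.0283. Of 5 control hexamers with the same bases, TTTTTA gave 0.0195 and ATTTTT 0.0097, and TATTTT, TTATTT and TTTATT gave 0.0022, -0.0012 and -0.0006. The shift is thus not shared by all U-rich hexamers, but 1 control, TTTTTA, matched the combined motif. None of the 5 controls reached TTTTAT alone, but TTTTTA is not independent of it, since TTTTTAT holds both. An effect of the motif and one of related sequence therefore cannot be told apart. The shift lay beyond the spread of matched random medians but is small beside the SD of 1.23 for single genes. Protein output, which CPEB proteins are known to regulate, is not analysed here.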
